A study of Homo sapiens with 6 samples.

How the data were processed

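RNA sequencing of the human acute myeloid leukaemia cell line Kasumi-1 was analysed in 6 libraries, 3 from cells given bovine serum albumin (BSA) as control and 3 from cells given recombinant human interleukin-10 (IL-10). Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Samples were grouped by their treatment label and named by the replicate number in their titles. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

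The deposited table of 27576 Ensembl genes is named as FPKM, but its values are a normalised signal: the authors deposited read counts divided by 1 size factor per library, as the values themselves show. In each library 100% of the values were whole multiples of 1 step within a tolerance of 0.01 read, and the reciprocal steps equalled median-of-ratios size factors of 0.851 to 1.12. The step of control replicate 2, 0.994, lies so close to 1 that an automatic check of the unit could not accept it, so the count test was also run without that library. The submitters' processing notes name GRCh38, hg38 and edgeR 3.18.1, with no role given. The aligner, counter, annotation and use of strand are not given in the sources used here. Recovered depth was 20750115 to 24222897 reads per library. Counting intervals and floors cover counting error only, and a count of 0 was given a floor of 3 reads per library.

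Of the gene identifiers, 26883 matched the table of gene names and 27052 matched GENCODE 29, whose GRCh38 coordinates are given. The plan, fixed before the data were examined, assumed FPKM. It was kept on the deposited values: limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), for 21946 genes with a value of at least 1 in at least 3 libraries, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are therefore on the log2(value + 1) scale, which understates those of low genes. Count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were added after the unit was known. Gene lists, 35 in number and fixed in advance, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Genes named are the 5 with the smallest p in each direction, since none passed the threshold, 9 genes fixed in advance, and up to 2 members of highest mean per list. Others are said to have been chosen after their values were seen.

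The replicate numbers were checked for pairing before any calls were compared. Deviations from the group means correlated between same-numbered libraries at 0.356, 0.602 and 0.726 across 11604 genes with a mean of at least 50, each over 0.1, so the numbers were taken to pair the samples and a fit with the replicate as a block was run. Of differently numbered libraries, control replicate 1 with IL-10 replicate 3 (0.203) and control replicate 3 with IL-10 replicate 1 (0.167) also exceeded 0.1. The others were at -0.695 to -0.304. The pairing comes from these values, since the labels give only a shared number.

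The tests were tried on simulated data: Poisson draws around the 6 libraries, with 200 genes of mean at least 50 changed by a known fold. For IL-10 against control, limma recovered 0% of genes changed 1.5-fold (20940 genes tested), 0% of those changed 2-fold (20998 genes) and 91.5% of those changed 4-fold (20963 genes). With the replicate block the shares were 0%, 50% and 100%. With pairs 1 and 3 only and the block, 77.5% of genes changed 1.5-fold were recovered (19478 genes tested), but 13.9% of the calls counted as false. These draws keep any difference already present between the libraries, which also counts as false when called. In a second simulation, of negative binomial draws with means shared by the libraries, limma recovered 0% of genes changed 1.5-fold (21065 genes tested), 23.5% of those changed 2-fold (21081 genes) and 98.5% of those changed 4-fold (21108 genes). There, pairs 1 and 3 with the block recovered 3.5% with 86% of calls false (19830 genes), 29% with 51.7% false (19821 genes) and 97% with 25.7% false (19793 genes). This second simulation held no pairing and took its spread from all 6 libraries, so it does not mimic the close pairs 1 and 3. When the STAT3-responsive list was raised 1.2-fold (21345 genes), camera gave an adjusted p of 1.68e-11, or 0.618 with an estimated correlation, and 3 other lists were also called. These draws keep the list's own median log2 fold change of 0.17, so the shift tested holds both. With an estimated correlation, rises of 1.5-fold and 2-fold gave 0.131 and 0.0484. For interferon-stimulated genes they gave 0.0226 and 0.00518, and with the block none of these 4 rises passed.

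Alternatives fixed in advance were other pseudocounts and filters, median-ratio and quantile scaling, no trend, sample weights, the replicate block and leaving out each library. Those added after seeing the data were the count tests, a filter of at least 10, pairs 1 and 3 only, equal totals, and a loess correction for GC content and transcript length. The correction was first run with each gene's longest transcript and, after its result had been seen, also with the APPRIS principal transcript, because the longest transcript of RPS29, which encodes a small protein, had 7062 bases. Lists of airway and liver markers were also added after the data were seen. The value of 1 marker is not reported here. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.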

Results

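Kasumi-1 is a leukaemia line that carries the t(8;21) fusion of RUNX1 and RUNX1T1. Its cells were grown in medium with 20% fetal bovine serum and treated for 72 h with 10 ng/ml of IL-10, a cytokine that signals through IL10RA, IL10RB and STAT3, or with 0.5% BSA. Each group had 3 libraries. Recovered depths were 23478195, 22429270 and 24222897 reads in control replicates 1 to 3 and 20750115, 23077693 and 22717860 reads in IL-10 replicates 1 to 3. Values are normalised read counts, given as mean ± SD (n = 3).

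In pairs 1 and 3 the libraries differed more by replicate than by treatment. The first principal component held 75.5% of the variance and set IL-10 replicate 2, at 58.9, apart from the other 5 libraries, at -23.6 to 10.98. Control and IL-10 libraries of pair 1 differed with a mean squared z of 2.77 over genes, where counting noise alone gives about 1, and those of pair 3 with 2.13. Among the other pairs of libraries without IL-10 replicate 2 the value was 16.1 to 50.9, and with that library 108 to 206. The value of 108 was that of pair 2. In pair 2, 3730 of 10505 genes with a mean of at least 100 differed by 1.5-fold or more, against 11 in pair 1 and 5 in pair 3.

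**Figure D1:**
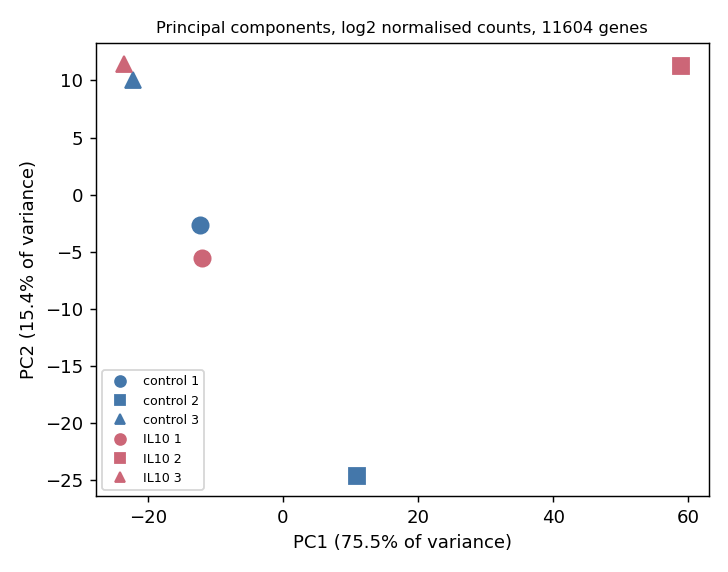
First and second principal components of log2 normalised counts of 11604 genes, 1 point per library; colour gives the group and shape the replicate number. IL-10 replicate 2 lies at 58.9 on the first component and the other 5 libraries between -23.6 and 10.98.

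Transcripts rich in GC were high in IL-10 replicate 2. Its median log2 deviation from the mean of the other 5 libraries was 0.86 in the 1158 genes highest in GC and -0.75 in the 1158 lowest, of 11575 genes. Across genes, which are not independent replicates, its deviation correlated with GC content at a Spearman rho of 0.770, against -0.630 to -0.207 in the other libraries. For each of those, IL-10 replicate 2 is part of the mean compared with, which by itself gives them the opposite sign. Their negative values therefore do not show an opposite GC trend of their own.

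**Figure D2:**
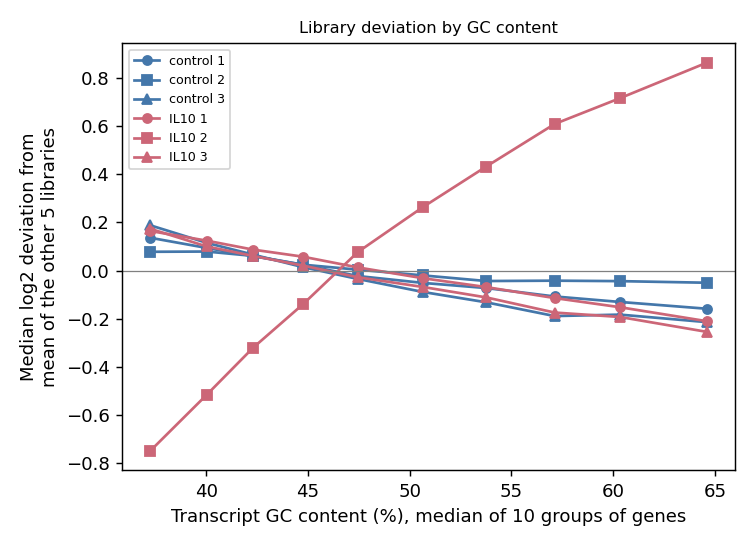
Median log2 deviation of each library from the mean of the other 5, for 10 groups of the 11575 genes ordered by GC content of the principal transcript; each line is 1 library. IL-10 replicate 2 runs from -0.75 in the lowest group to 0.86 in the highest. For every other library the mean compared with includes IL-10 replicate 2, which by itself tilts its line the opposite way.

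The comparison of IL-10 with control asks which transcripts differed after 72 h of the cytokine. IL10RA, the ligand-binding receptor chain, stood at 11.1 ± 5.34 in control and 16.3 ± 4.14 with IL-10, and IL10RB at 500.3 ± 97.6 and 513 ± 50.3. STAT3 stood at 4762 ± 225 and 5565 ± 1141, and its target SOCS3, a feedback inhibitor of cytokine signalling, at 121 ± 42.4 and 146 ± 17.8. BCL3, an NF-kB cofactor induced by IL-10 in macrophages, stood at 160.4 ± 8.39 and 231 ± 79.7. None of these passed the threshold in limma (adjusted p = 0.982 or above). The log2 fold change of SOCS3 was 0.33 (95% interval -0.33 to 1.00) and that of BCL3 0.47 (-0.11 to 1.06), and that of IL10RB 0.05 (-0.39 to 0.49). The log2 ratio of SOCS3 was -0.07, 1.01 and 0.06 in pairs 1, 2 and 3, and that of BCL3 -0.06, 1.05 and 0.42. IL10RA was low, at 4.97 to 20.9 in single libraries. Its log2 fold change was 0.62 (95% interval -0.40 to 1.64), with log2 ratios of -0.20, 1.45 and 0.61 in pairs 1, 2 and 3. SOCS3 had 0.02 without control replicate 2 and changed sign in 2 settings, BCL3 had 0.21 without IL-10 replicate 2, and IL10RB changed sign in 7 settings.

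The stem-cell factor POU5F1, whose reads can be shared with its pseudogenes, stood at 11.4 ± 3.19 and 13.3 ± 4.46. RUNX1T1 stood at 3789 ± 123 and 3593 ± 453, the receptor gene KIT at 44584 ± 8765 and 41172 ± 11920, and the progenitor marker CD34 at 12504 ± 1038 and 13014 ± 1719. These differences were also within the spread between replicates.

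**Figure D3:**
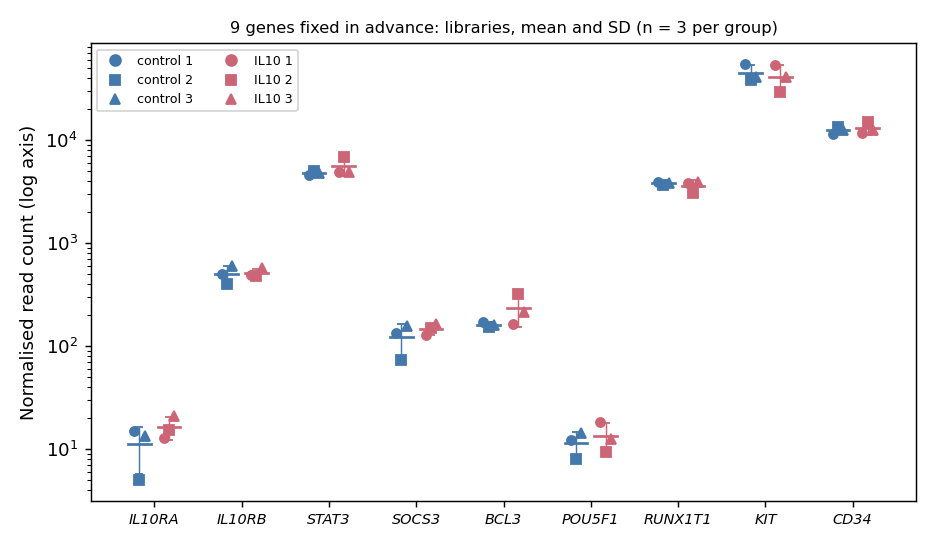
Normalised read counts, on a log axis, of the 9 genes fixed in advance; points are libraries, horizontal bars group means and error bars SD (n = 3 per group). None passed the threshold; IL10RA stood at 11.1 and 16.3 and KIT at 44584 and 41172 in control and IL-10.

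Over all 21946 genes, limma placed 0 past the threshold, with 344 at an unadjusted p under 0.05 and a smallest adjusted p of 0.982. edgeR also called 0 (257 unadjusted) and DESeq2 0 (94 unadjusted). The groups did not overlap in 1289 genes (5.87%, where chance gives 10%). The median 95% interval reached 0.49 on the log2 scale to either side for genes with a mean of at least 50, and in 2 simulations limma recovered 0% of genes changed 1.5-fold, 0% and 23.5% of those changed 2-fold, and 91.5% and 98.5% of those changed 4-fold. With pairs 1 and 3 only and the replicate block, a fit with 1 residual degree of freedom chosen after seeing the data, 11 genes passed (10 higher and 1 lower).

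Among the genes with the smallest p, the airway secretory genes SCGB3A1 and BPIFA1 had lower values in every IL-10 library. SCGB3A1 (ENSG00000161055, chromosome 5, 180590103 to 180591540), which encodes a secretoglobin, stood at 69.1 ± 9.82 and 23.9 ± 0.684, a log2 fold change of -1.48 (SE 0.25, adjusted p = 0.982 in limma). It passed only in the fit of pairs 1 and 3 with the block (adjusted p = 0.00177). BPIFA1 (ENSG00000198183, chromosome 20, 33235995 to 33243311), which encodes a secreted airway protein, stood at 41.5 ± 1.34 and 17.6 ± 4.56, a log2 fold change of -1.22 (SE 0.29, adjusted p = 0.982). SLPI, at 48.7 ± 9.17 and 23.7 ± 1.91, and WFDC2, at 26.6 ± 2.43 and 14.5 ± 2.43, were chosen after their values were seen.

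The other genes of smallest p were close to the detection floor and none passed the threshold. CST1, a cystatin gene, had 0 reads in control and 16 with IL-10, at least 2.02-fold higher against a floor of 3 reads per library. MAGEB2, a cancer-testis gene, had 26 reads in control and 1 with IL-10, a ratio of 23.1 with an exact 95% interval of 3.79 to 945. CENPS-CORT, a read-through gene that overlaps CENPS, had 2 and 15 reads, a ratio of 8.46 (1.97 to 76.3). ENSG00000268056, an antisense gene, had 13 and 0 reads, at least 1.29-fold lower, and ENSG00000280326 had 17 and 1, a ratio of 15.1 (2.36 to 630). The pseudogene RPL21P35 stood at 3.98 ± 2.13 and 13.5 ± 3.31, and can share reads with RPL21. Metazoa_SRP and ENSG00000266955 held identical values, 0 reads in control and 9 with IL-10, with both groups at or under the floor.

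Transcripts of liver genes, chosen after their values were seen, were present in both replicate 2 libraries. TF, which encodes transferrin, stood at 208.8 in control replicate 2 and 85.8 in IL-10 replicate 2, and ALB, which encodes albumin, at 112 and 31.7. In the other 4 libraries TF was at most 3.73 and ALB at most 0.89.

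**Figure D4:**
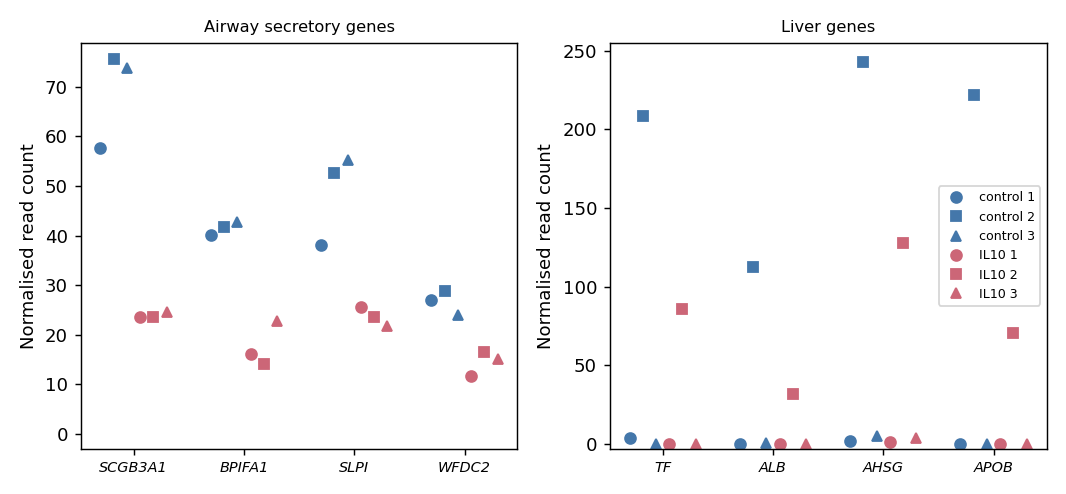
Normalised read counts of 4 airway secretory genes and 4 liver genes, 1 point per library, coloured by group and shaped by replicate number. SCGB3A1 stood at 57.8 to 75.6 in control and 23.5 to 24.7 with IL-10, and AHSG at 243 and 128 in the replicate 2 libraries and at most 5.34 in the others.

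Cytosolic ribosomal protein genes were the 1 list of 35 to pass the threshold in camera (adjusted p = 0.00059), but not with an estimated correlation (0.846) or with fry (0.905). The median ratio was 0.08 in pair 1, 0.48 in pair 2 and -0.01 in pair 3, and without IL-10 replicate 2, the library that stood apart, the median was 0.04 and the adjusted p 0.425. With all libraries the 30 measured members had positive log2 fold changes, with a median of 0.19, and 0 passed singly. RPS3 stood at 85011 ± 3427 and 99227 ± 22426 and RPL8 at 75808 ± 3706 and 97335 ± 35731.

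The other 34 lists did not pass, and with an estimated correlation no list did (adjusted p = 0.846 or above). That test excludes little: in simulation it also missed the STAT3-responsive list raised 1.5-fold (adjusted p = 0.131). Of the 31 lists with a positive median, 30 had their largest pair median, in absolute value, in pair 2, which holds IL-10 replicate 2, and 28 had medians under 0.1 in pairs 1 and 3. No list had a member past the threshold, whether over all genes or adjusted over the list alone, with or without the block. Of 33 STAT3-responsive genes, 25 had a positive value, with a median of 0.17 (camera adjusted p = 0.108). Without IL-10 replicate 3 the list passed in camera (adjusted p = 0.0313), and without IL-10 replicate 2 it had 0.848; over all libraries the adjusted p was 0.846 with an estimated correlation. Their median was -0.01 in pair 1, 0.52 in pair 2 and -0.01 in pair 3. MYC, the most abundant, stood at 19244 ± 3070 and 22817 ± 10028, and BCL2, an inhibitor of apoptosis, at 5757 ± 90.3 and 5754 ± 390.04. The 17 receptor and JAK-STAT components had a median of 0.05 and an adjusted p of 0.658.

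Interferon-stimulated genes had a median of -0.09 over 36 members (adjusted p = 0.692), with LY6E at 4729 ± 144 and 6091 ± 2859 and IFITM3 at 3213 ± 142 and 4328 ± 1882. Immediate-early genes had a median of 0.17 (0.0964; 0.31 and 0.0141 without IL-10 replicate 1, and an adjusted p of 0.846 with an estimated correlation), NF-kB and inflammatory cytokine genes 0.09 (0.545), and HLA class II genes 0.02 (0.829). CD74, the class II invariant chain, stood at 2451 ± 30.2 and 3049 ± 965. For HLA class II, neutrophil granule, monocyte and p53 target lists the median, mean and test differed in sign.

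Leukaemia and stem-cell lists also stayed short of the threshold. Genes associated with t(8;21) leukaemia had a median of 0.06 (adjusted p = 0.617), the LSC17 leukaemic stem cell signature 0.16 (0.624) and pluripotency factors 0.16 (0.321). Neutrophil granule genes had a median of 0.12 (0.7996), with MPO, the myeloperoxidase gene, at 102644 ± 44038 and 122627 ± 48624. Monocyte markers had 0.01 (0.882), mast cell markers 0.07 (0.692), erythroid and megakaryocyte markers 0.01 (0.617), T and NK cell markers 0.20 (0.601) and B cell markers 0.22 (0.141). Fibroblast, endothelial and epithelial markers had -0.09 (0.658). KRT8, an epithelial keratin also abundant in liver cells, stood at 59.03 ± 84.1 and 32.95 ± 46.8, with its high values in the replicate 2 libraries.

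Of the growth and metabolism lists, nuclear-encoded oxidative phosphorylation genes came nearest, with 28 of 32 members positive and a median of 0.12 (adjusted p = 0.0632, or 0.846 with an estimated correlation), and medians of 0.06, 0.31 and -0.01 in pairs 1, 2 and 3. Replication-dependent histones had a median of 0.44 over 9 members (0.0794, or 0.0448 with quantile normalization and 0.846 with an estimated correlation), and mitochondrial-encoded genes 0.13 (0.22). The histone medians were 0.23, 0.58 and 0.45 in pairs 1, 2 and 3, with a camera adjusted p of 0.872 in pairs 1 and 3 with the block. S phase genes had 0.10 (0.267), with MCM7 at 13297 ± 1738 and 16448 ± 7275, and G2/M genes -0.10 (0.545), with TOP2A at 19329 ± 382 and 16489 ± 5720. Ribosome biogenesis genes had 0.12 (0.658), or 0.27 (0.0469) without control replicate 2 and 0.24 (0.0355) without IL-10 replicate 3. Cholesterol genes had 0.14 (0.219), or 0.25 (0.00881) without control replicate 1 and 0.25 (0.0355) without IL-10 replicate 3. Glycolysis and hypoxia genes had 0.15 (0.22), or 0.39 (0.000237) without control replicate 3 and 0.28 (0.0122) without IL-10 replicate 2. With an estimated correlation over all libraries the adjusted p of these 3 lists was 0.934, 0.846 and 0.846. Ribosome biogenesis genes had medians of 0.06, 0.20 and -0.02 in pairs 1, 2 and 3. Cholesterol genes had -0.06, 0.53 and 0.02, and glycolysis and hypoxia genes -0.03, 0.44 and 0.03. Leaving out 1 library leaves its partner without a pair, so differences between replicates enter those fits. Without IL-10 replicate 3, S phase genes (0.25, adjusted p = 0.0313) and mitochondrial-encoded genes (0.33, 0.014) also passed, both with 0.846 with an estimated correlation. Oxidative phosphorylation genes passed without that library too (0.25, 0.00221), and without control replicate 2 (0.14, 0.0469). The medians were 0.10 for fatty acid synthesis genes (0.658) and 0.09 for PI3K-AKT-mTOR components (0.731).

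Stress and survival lists had medians of 0.07 for the ATF4 amino-acid response (adjusted p = 0.658), 0.08 for endoplasmic reticulum chaperones (0.731), 0.09 for heat shock genes (0.862), 0.07 for p53 targets (0.731), 0.04 for apoptosis regulators (0.658), 0.13 for NRF2-linked genes (0.601) and 0.15 for lysosome and autophagy genes (0.336). Nuclear-retained and small RNA genes, which follow RNA quality, had -0.04 (0.829), with NEAT1 at 11072 ± 3573 and 9793 ± 5061.

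**Figure D5:**
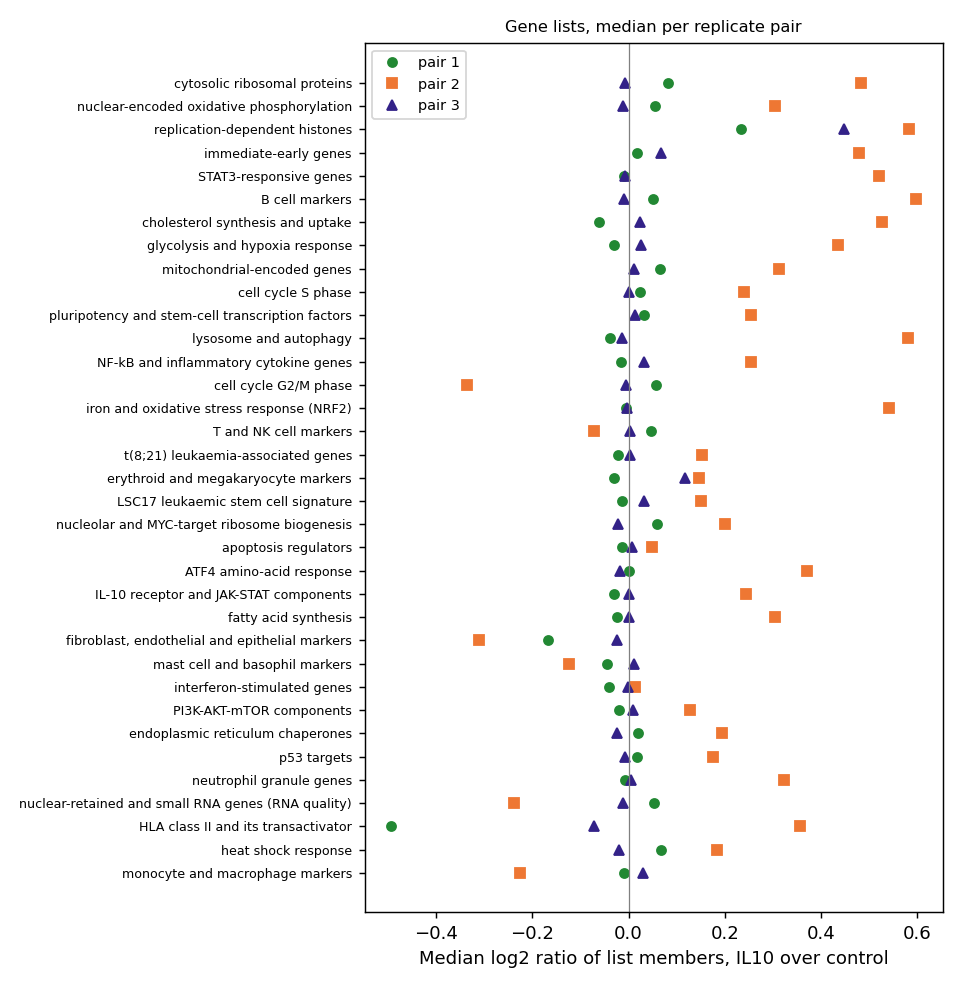
Median log2 ratio of IL-10 over control for the members of each of 35 gene lists, 1 point per replicate pair, ordered by camera p. Ribosomal protein genes have medians of 0.08, 0.48 and -0.01 in pairs 1, 2 and 3.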

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

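The count of genes past the threshold in limma stayed at 0 under every setting fixed in advance, leaving out each library included, and in edgeR and DESeq2, with and without the replicate block. The exception, added after seeing the data, was pairs 1 and 3 only with the replicate block: 11 genes, 10 higher and 1 lower, of which 1 changed at least 2-fold. That fit has 4 libraries and 1 residual degree of freedom. Of its calls, 8.26% to 13.9% counted as false in draws around these libraries and 25.7% to 86% in draws with shared means. The draws around these libraries keep any difference already present in them and count it as false, so the first range does not measure how many of these calls are false. The draws with shared means hold no pairing and take their spread from all 6 libraries, IL-10 replicate 2 included. The second range therefore does not measure it either. The replicate block on all 6 libraries gave 0 genes (512 at an unadjusted p under 0.05) and changed no other call. The 1 gene list past the threshold became 2 with a pseudocount of 0.1, a filter of at least 5 or of at least 10, the replicate block with the latter, or the GC and length correction by either choice of transcript. The second was nuclear-encoded oxidative phosphorylation, which passed in 10 of 27 alternatives (adjusted p from 0.00221 to 0.905) and had 0.846 with an estimated correlation. It became 3, with mitochondrial-encoded genes, with that correction and the block. It became 0 with sample weights, pairs 1 and 3 only with or without the block, an estimated correlation with or without the block, and fry. Leaving out 1 library gave 1 to 7 lists: STAT3-responsive genes were among the 7 without IL-10 replicate 3 (adjusted p = 0.0313; 0.0313 to 0.985 over all settings), and glycolysis and hypoxia was 1 of 2 without control replicate 3 (0.000237) and the only list without IL-10 replicate 2 (0.0122; 0.000237 to 0.985). The cause was not tested, except that fewer libraries entered some fits. Leaving out 1 library also left its partner without a pair. In pairs 1 and 3 with the block, the glycolysis and hypoxia list had an adjusted p of 0.896 in camera. Ribosomal protein genes passed in 19 of 27 alternatives (adjusted p from 3.3e-05 to 0.905), but not without IL-10 replicate 2 (0.425) or with quantile normalization (0.898), where replication-dependent histones were the 1 list past the threshold (0.0448; 0.0448 to 0.905), and kept a positive direction in all 27. No called result reversed; of results past no threshold in either fit, 24 gene and 96 list comparisons changed sign. Equal totals moved the median log2 fold change of all genes from 0.02 to -0.08. Correcting by the principal transcript was added after the longest had been tried, and left the same lists past the threshold. In genes of mean at least 50 the median residual SD was 0.27 on the log2 scale, against 0.05 from counting alone; at means of 50 to 100 the medians were 0.34 and 0.17, so depth limits those more.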

Other observations

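Ribosomal protein genes were 5 of the 11 genes past the threshold in pairs 1 and 3 with the replicate block: RPS29 (log2 fold change 0.24), RPL23A (0.27), RPL38 (0.17), RPL37 (0.16) and RPL37A (0.15). They were noticed after the calls were seen, and no test of their share is given. The others were SCGB3A1 (-1.40), CNIH3 (0.85), the pseudogene RPSAP47 (0.58), GGCT (0.36), ENSG00000277105 (0.25) and the mitochondrial MT-ND4L (0.22). The whole ribosomal protein list did not pass in that fit (adjusted p = 0.516). Across 10505 genes with a mean of at least 100, the log2 ratios of pairs 1 and 3 correlated at r = -0.00514. Of these genes, 0 differed 1.5-fold or more in both pairs. Below that mean some did: SCGB3A1 had log2 ratios of -1.26 and -1.54 in pairs 1 and 3, and BPIFA1 -1.27 and -0.88. Genes are not independent replicates.

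Of the tests that follow, those of depth and of liver RNA in IL-10 replicate 2, and of SCGB3A1, were chosen only after the result was seen, as were the marker lists. All 10 splits of the 6 libraries into groups of 3 gave as many genes past the threshold as the real one, 0, and the highest other was 0. With a real count of 0 no split can give fewer, so this comparison decides nothing. Besides, 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 344 genes and the highest other 2711, which points to a structure of the samples. The 3 other splits that part all 3 pairs gave 283, 283 and 288 genes, or 429, 437 and 485 against 512 with the block.

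IL-10 replicate 2 stood apart from the other 5 libraries. Its depth, 23.1 M reads, lay within their range, and its summed liver markers were 0.504 times those of control replicate 2, which stood apart less, so depth or liver RNA as the whole cause is argued against. The spread of pair 2 did not return in the other pairs. The slope of the mean log2 ratio of pairs 1 and 3 on that of pair 2 was -0.0162 (bootstrap 95% interval over genes -0.0191 to -0.0134). The interval treats genes as independent and does not measure the spread between libraries. A slope this small argues against an IL-10 effect shared by the pairs as the source of the spread of pair 2. It says little of a shared effect on fewer genes, since the pair 2 ratio followed GC content (Spearman rho 0.842). GC and length bias may account for part: the median deviation over the largest of another library was 2.64 before and 1.78 after the loess correction, between the bounds of 1.5 and 2 set in advance. The longest transcript gave 1.77, and medians over a grid of GC and length, which were run first in place of the planned loess, gave 1.72, so the rest cannot be told apart from a difference in the culture or library.

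A set of 12 airway secretory transcripts was looked at when low values of some with IL-10 had been noticed. Their sum was 0.663, 0.645 and 0.582 of control in pairs 1, 2 and 3. This was no test of airway genes as a group. The fall was not shared by all members. MUC5AC stood at 42.25 ± 7.36 in control and 50.16 ± 14.1 with IL-10, and AGR2 at 9.46 ± 2.41 and 9.39 ± 1.74. Reads from airway epithelium predicted a fall in a second set of markers not looked at before, but 16 of them summed to 1.12 over the pairs (1.04, 1.24 and 1.10), past the bound set in advance. That source stays open all the same, since S100P and MUC1 held 72.9% of the control sum; without them the ratio was also 1.12, over genes near the floor, and markers above 200 (FCGBP and CEACAM6), a limit set in the test and not in its prediction, were left out. The 11 ciliated-cell markers went both ways (0.749, 1.32 and 0.856). Single members did too: FOXJ1, chosen after its values were seen, stood at 20.6 ± 2.73 in control and 10.8 ± 2.95 with IL-10. CCDC78, the most abundant of the 11, stood at 33.7 ± 10.4 and 42.3 ± 8.48. An effect of IL-10 on the airway secretory genes is neither shown nor excluded. SCGB3A1 had an adjusted p of 0.982 in limma. Its interval of -2.05 to -0.92 is not adjusted for its choice as a gene of smallest p, so it decides nothing. Treatment also cannot be told apart from another difference between the groups of libraries.

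Liver transcripts were found in both replicate 2 libraries, and reads from liver-like cells are a candidate source. A second set of 18 liver markers, not looked at before, summed to 1020 in control replicate 2 and 532 in IL-10 replicate 2 and to at most 41.8 elsewhere, so the lower was 12.7 times the highest other library, past the 5 set in advance. AHSG stood at 243 and 128 and APOB at 222 and 70.5, but HP and CYP2E1, abundant in adult liver, were at most 7.12 in any library. Expression by the cells of replicate 2 stays open: the second set's ratio of IL-10 to control, 0.522, matched the 0.504 of the first within counting error, the bound set in advance against it. That bound was wrong, since in a check chosen after the result was seen 68.2% of 1000 sets of other genes, drawn to match the markers in reads, also gave 2 ratios that matched. The summed ratios also hide differences between markers. In another check written after the result, 15 single markers had ratios of 0.282 to 1.03, which rose with GC content (Spearman rho 0.636). A chi-square test of equal ratios gave p = 1.28e-06, or 0.0317 after allowing for the GC trend of all genes in pair 2. That test assumes counting error alone, whereas genes in general differed far beyond it between these 2 libraries (mean squared z of 108). Its p-values therefore do not decide between liver-like cells and expression by the cells of replicate 2.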
